A study of Rattus norvegicus with 48 samples.

How the data were processed

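RNA from the extensor digitorum longus, a fast muscle of the lower leg, was measured on 48 Affymetrix Rat Gene ST 2.1 arrays, 1 per rat except where stated. HCR and LCR are the usual names of rat lines bred for high and for low running capacity, and the labels give only the abbreviations. The labels place 6 arrays in each of 8 groups, formed by line (HCR or LCR), age (young or old) and state (at rest or exhausted). They give neither ages in months nor the time between the end of the run and tissue collection, and no batch, date or pairing. Each title carries an animal number, so that replicates of a group are different rats. The title of young HCR rest replicate 6 names 2 animals. Replicate numbers follow accession order and only name an array.

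According to the labels, total RNA from frozen tissue was extracted with Trizol, treated with DNase and cleaned on RNeasy columns, and biotin-labelled cDNA was made from 400 ng of it. The deposited values are on a log2 scale, 1 per probe set and array. The series' design text credits Expression Console, and the submitters' processing notes name RMA and oligo without versions; which of these made the deposited values is not given in the sources used here. RMA subtracts background, makes the arrays' intensity distributions alike by quantile normalization and summarises the probes of a set on the log2 scale. Values ran from 0.569 to 13.6, and column medians from 4.47 to 4.59. Small shifts between arrays therefore remained over all probe sets, and shifts common to most genes cannot be read from such values. An array gives no read depth: the number of arrays and the signal over background limit the precision.

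The table held 36685 probe sets, of which 15653 had a gene name in the platform's table. The 14824 probe sets that name exactly 1 gene were used; 829 name several genes and 21032 none. Entrez identifiers matched 14670 of the 14824 to current rat gene records, symbols matched 89 more, 65 had no match, and the update changed 0 symbols. Of several probe sets of a gene the brightest stood for it, which concerned 234 of 14557 genes. In 4 of the 234 genes, 2 probe sets moved in opposite directions after exercise at an unadjusted p below 0.05; none did so between lines or ages. A gene was tested if its value exceeded 4.54, the median of all values, in at least 6 arrays. This left 9558 genes and dropped 4999. No genome came with the data, so that no coordinates are given.

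Differences were tested with limma 3.58.1 in R 4.3.3, and Python 3.11.15 served for figures. A single model held a mean for each of the 8 groups, with default empirical Bayes moderation (40 residual and 3.77 prior degrees of freedom). All tests were two-sided, with Benjamini-Hochberg adjustment within each of 17 comparisons and a threshold of 0.05. Of these, 13 compare groups: exhausted against rest, HCR against LCR and old against young, as averages and within single strata of line and age. The other 4 are interactions, that is, tests of whether one difference itself differs between groups. Errors given with log2 changes are standard errors (SE) of that model, and those given with group means are standard deviations (SD).

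Gene lists were tested with limma's camera, which compares a list's genes with all others, at a preset correlation between genes of 0.01. The test was repeated with the correlation estimated from the data. The 36 lists, 22 of pathways or gene families and 14 of cell type or tissue markers, were written down before the data were examined, as were the comparisons, the filter and the rule for named genes. A list was tested if at least 5 members were measured, which held for 32. Over the 17 comparisons 196 list results passed the threshold at the preset correlation; 33 of them also passed with an estimated correlation and 163 did not. In none of the 196 did the median or mean change of the members differ in sign from the test.

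Named genes were chosen by rule. For each of the 3 main averages these are the 12 largest rises and the 12 largest falls past the threshold with one sign in every stratum. Each comparison within a stratum, or between lines or ages after the run, adds 3 per direction, and each interaction up to 5 per direction by smallest p. Up to 4 members of a list are named if past the threshold, or up to 2 others if none was. Predicted genes and unnamed loci were left out of the names, not of the counts.

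The procedure was tested on simulated data with the real genes' means and residual spread, but with genes drawn independently of each other. In these data 200 of 9558 genes were changed. For exhausted against rest over all strata, 94.0% of changes of 0.5 on the log2 scale were recovered and 100% of those of 1 and 2, with 6 false calls among 202. Within young HCR alone the shares were 62.7%, 92.5% and 100%, with 3 false calls among 173. For HCR against LCR at rest they were 88.1%, 98.5% and 100%, with 7 of 198 false. For old against young at rest they were 86.6%, 98.5% and 100%, with 9 of 199 false. For the line by exercise interaction they were 68.7%, 92.5% and 97.0%, with 6 of 178 false. A list of 15 members shifted by 0.3 reached an adjusted p of 2.52e-35, and 0 of 29 lists without shared members were called. Because the simulated genes were independent, this does not show how often lists of correlated genes are called falsely.

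Alternatives covered the filter, quantile normalization on top, median centring of each array, array quality weights, the variance model, the handling of several probe sets, and the first principal component of the residuals. The mean of slow fibre markers or of adipocyte markers as a covariate, an additive model, fits to the 12 arrays compared, and leaving out each array in turn were also planned. After the data were seen, 3 more were added: leaving out 3 arrays that stand apart, and the mean of tendon markers or of liver transcripts as a covariate. Groups were also formed by random relabelling, 100 arrangements for each comparison with the real one included. Probe sets without a single gene name took no part in the comparisons.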

Results

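Expression of 9558 genes was compared on 48 arrays of rat extensor digitorum longus. The rats came from the HCR and LCR lines, were young or old, and were sampled at rest or after a run to exhaustion, with 6 arrays in each of the 8 groups. Pairs of arrays of the same group correlated at between 0.948 and 0.979. Old HCR exhausted replicate 1, young HCR exhausted replicate 1 and old LCR rest replicate 2 had the highest lower quartiles of all arrays, at 3.28, 3.24 and 3.24, and limma quality weights of 0.360, 0.402 and 0.323. All 3 stayed in the comparisons.

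Exhausted rats were compared with rested rats first, averaged over the 4 strata of line and age (24 against 24 arrays), to see how the muscle responds to a single exhausting run. Transcription factors and signalling genes that respond quickly to stimuli rose most. Nr4a2, an orphan nuclear receptor, rose by 2.42 ± 0.17 on the log2 scale (SE; 5.34-fold, adjusted p = 8.98e-15), the AP-1 factor Junb by 2.03 ± 0.13 and Sik1, a salt-inducible kinase, by 1.99 ± 0.13. Apold1, an early response gene of endothelial cells, rose by 2.02 ± 0.17, Zfp36, which destabilises mRNAs, by 1.68 ± 0.10, and Ptgs2, the inducible cyclooxygenase, by 1.58 ± 0.10. Ddit4, an inhibitor of mTORC1, rose by 1.54 ± 0.14, and Coq10b, Arrdc2, Stc1, Klf4 and Hes1 by between 1.29 and 1.58. Each of these 12 was higher than the mean of the matching rest group in 23 or 24 of the 24 exhausted arrays.

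By list, 20 of 25 measured immediate early genes rose and none fell (20 higher and 1 lower when adjusted over the list alone), with a median change of 0.91 (camera adjusted p = 1.04e-37, and 6.2e-05 with an estimated correlation). All 12 measured glucocorticoid and FoxO target genes rose, both over all genes and adjusted over the list alone, by a median of 0.60 (adjusted p = 4.12e-26, and 1.67e-06 with an estimated correlation). Per1 rose by 1.26, Irs2 by 1.07 and Errfi1 by 1.05. Inflammatory signalling had 7 of 15 members higher and 1 lower (9 and 2 adjusted over the list alone), among them Ptgs2, Nfkbia at 0.77, Cebpb at 0.53 and Il6r at 0.52. The list as a whole was higher (adjusted p = 9.68e-07, and 0.0023 with an estimated correlation). Of 18 heat shock proteins and chaperones 7 rose (8 adjusted over the list alone), led by Dnajb1 at 0.78 and Hspa1b at 0.59 (adjusted p = 5.68e-05, and adjusted p = 0.247 with an estimated correlation). Macrophage markers had 5 of 10 members higher (6 adjusted over the list alone), with Lyve1 at 0.57 and the complement component C1qb at 0.45 (adjusted p = 0.000485, and adjusted p = 0.335 with an estimated correlation).

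The largest falls were of another kind. Lpar6, a receptor for lysophosphatidic acid, fell by 1.01 ± 0.09 (adjusted p = 2.22e-12), Rgs4, a regulator of G-protein signalling, by 0.80 ± 0.08, and Tnfsf10, the death ligand TRAIL, by 0.69 ± 0.10. The other 9 named falls were of Alb, Gc, C3, Pzp, Crp, Ambp, Hp, Apob and Serpina3c, which encode plasma proteins made mostly by the liver. Alb, the gene of serum albumin, fell by 1.87 ± 0.55 (3.65-fold lower, adjusted p = 0.0153) and was lower in at least 20 of 24 arrays, as were the other named falls. With the mean of liver transcripts as a covariate Alb was at -0.38 (adjusted p = 0.390) and none of the 9 passed the threshold. That mean tracks these genes and may include them, so that this decides nothing. Without young LCR rest replicate 5 or old HCR rest replicate 5 the calls of Pzp, Ambp and Apob were lost (Pzp without any of 7 arrays and Apob of 12), and that of Serpina3c without any of 24. A few rest arrays carried the highest values, but Alb also reached 9.79 in old HCR exhausted replicate 5 and 9.76 in young LCR exhausted replicate 3.

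**Figure D1:**
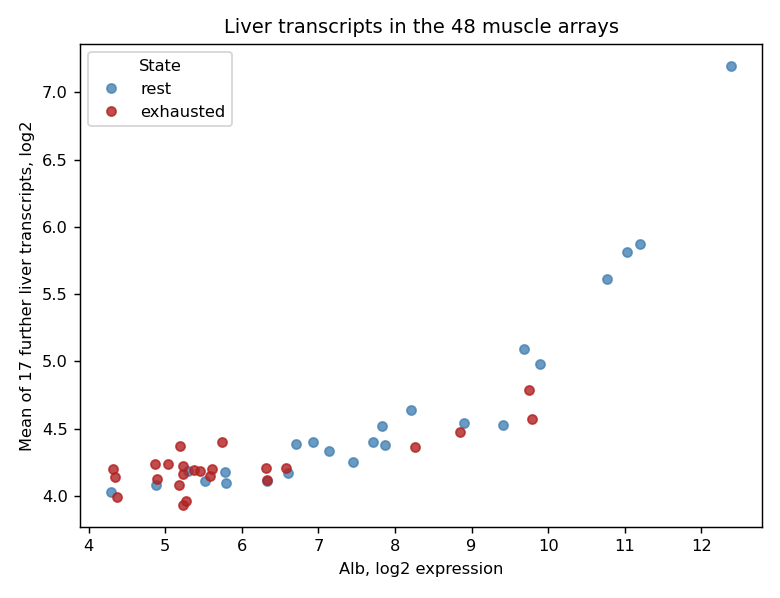
Level of Alb (x axis, log2) against the mean of 17 further liver transcripts (y axis, log2) in the 48 arrays, with rest arrays in blue and exhausted arrays in red. Alb reached 12.4 in young HCR rest replicate 3, 11.2 in old LCR rest replicate 2 and 11.0 in young LCR rest replicate 5, and its lowest value was 4.30.

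Altogether 1542 genes changed after the run, 623 up and 919 down, of which 62 rose and 18 fell at least 1.5-fold. Quantile normalization on top turned this split into 751 up and 791 down, and median centring of the arrays into 822 up and 659 down, so that the direction of small changes depended on scaling. Averaged over the strata, the lists of energy metabolism moved little: 0 of 19 fatty acid oxidation enzymes changed (adjusted p = 0.423), 1 of 15 citric acid cycle enzymes fell (adjusted p = 0.384), and oxidative phosphorylation subunits had 3 of 60 higher and 4 lower (adjusted p = 0.481). No measured member changed among 24 extracellular matrix genes (adjusted p = 0.565), 10 slow muscle fibre markers (adjusted p = 0.838), 7 tendon markers (adjusted p = 0.481), 9 adipocyte markers (adjusted p = 0.139), 10 p53 and senescence genes (adjusted p = 0.573) or 6 Schwann cell and nerve markers (adjusted p = 0.971).

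**Figure D2:**
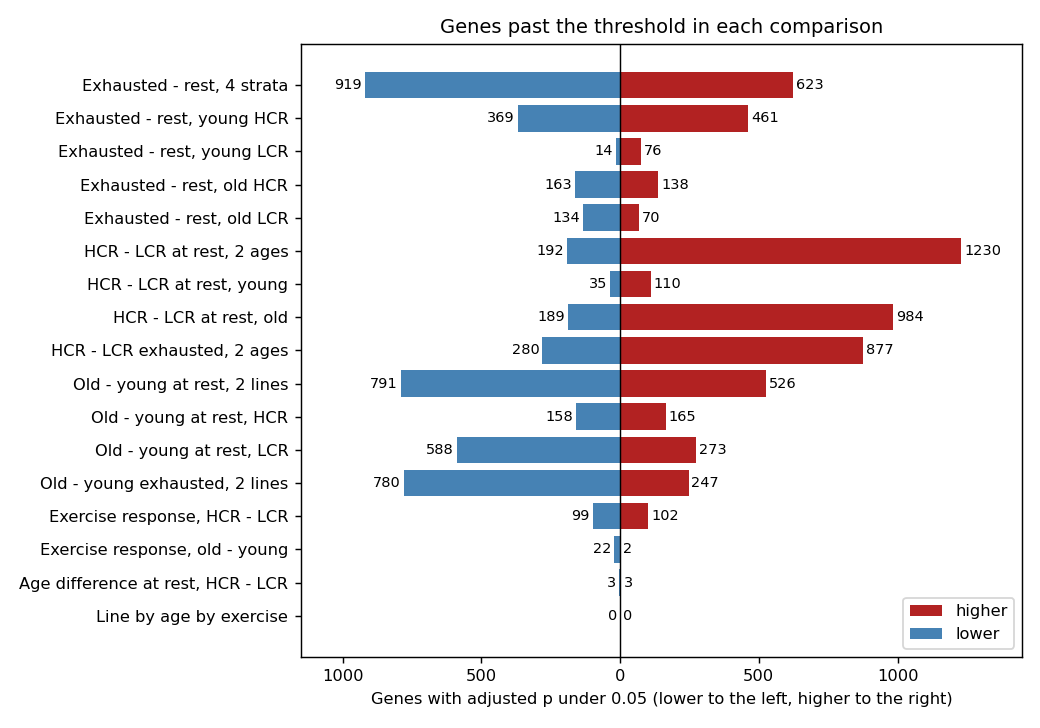
Number of genes with an adjusted p below 0.05 in each of the 17 comparisons, lower to the left in blue and higher to the right in red. The response to exercise covered 830 genes in young HCR, 90 in young LCR, 301 in old HCR and 204 in old LCR; quantile normalization moved the split between up and down by over 10 points in several comparisons, among them HCR against LCR at rest (1230 and 192 as deposited, 476 and 385 after it).

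Within single strata the response was read from 6 exhausted against 6 rested rats. In young HCR, 461 genes rose and 369 fell. Nr4a2 rose by 3.64 ± 0.34 (12.4-fold), Junb by 3.18 ± 0.26 and the metallothionein gene Mt2A by 3.06 ± 0.39, with 6 of 6 arrays higher each. Lpar6 fell by 1.80 ± 0.17, the apelin receptor gene Aplnr by 1.79 ± 0.19 and the arachidonic acid epoxygenase gene Cyp2c23 by 1.37 ± 0.40. All 12 glucocorticoid and FoxO target genes rose, with a median of 1.02 (12 adjusted over the list alone; adjusted p = 8.3e-07 with an estimated correlation). Of 25 immediate early genes 18 rose, with a median of 1.38 (20 adjusted over the list alone; adjusted p = 0.000259 with an estimated correlation). Pdk4, which restrains glucose oxidation, rose by 1.45 and the uncoupling protein gene Ucp3 by 1.27 in the PPAR and fasting list, where 4 of 18 members rose and 1 fell (7 and 1 adjusted over the list alone; adjusted p = 0.00293, and adjusted p = 0.437 with an estimated correlation). Tendon markers were also higher in this group, 3 of 7 past the threshold (5 adjusted over the list alone) with Chad at 1.55 and Fmod at 1.48 (adjusted p = 0.000725, and adjusted p = 0.227 with an estimated correlation). The Cyp2c23 call was lost without young HCR rest replicate 3, with a change of -0.79, or without young HCR exhausted replicate 2. The former array had the highest Alb of all (12.4), and with the liver mean as a covariate the Cyp2c23 change was -0.75, still past the threshold.

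Young LCR rats responded with 76 rises and 14 falls. Fos rose by 2.31 ± 0.44, Apold1 by 2.12 ± 0.34 and Egr1 by 2.10 ± 0.39. The transferrin receptor gene Tfrc fell by 0.75 ± 0.16, Lpar6 by 0.70 ± 0.17 and Hacd1, of very long chain fatty acid synthesis, by 0.49 ± 0.13. Immediate early genes had 14 of 25 members higher (22 adjusted over the list alone; adjusted p = 7.62e-05 with an estimated correlation). Glucocorticoid and FoxO target genes had 5 of 12 higher (9 adjusted over the list alone; adjusted p = 0.000129 with an estimated correlation). The count of 90 was sensitive to single arrays: it was 45, 56 and 58 without exhausted replicates 2, 1 and 6, and 141, 52 and 48 without rest replicates 1, 2 and 5. The Hacd1 call was lost without any of 18 arrays and the Lpar6 call without any of 7.

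In old HCR rats 138 genes rose and 163 fell. After quantile normalization 171 rose and 110 fell, and after median centring 191 and 83. Nr4a2 rose by 2.67 ± 0.34, the glycoprotein hormone gene Stc1 by 2.54 ± 0.28 and Junb by 2.41 ± 0.26, and Aplnr fell by 1.49 ± 0.19, Lpar6 (-1.40 ± 0.17) also fell, and Rgs4 fell by 1.24 ± 0.17. Immediate early genes had 12 of 25 members higher (13 higher and 1 lower adjusted over the list alone; adjusted p = 0.0101 with an estimated correlation). Glucocorticoid and FoxO target genes had 6 of 12 higher (6 adjusted over the list alone; adjusted p = 7.73e-05 with an estimated correlation). Metabolic lists lay lower in old HCR after the run: fatty acid oxidation enzymes by a median of -0.17 with 0 of 19 past the threshold (0 adjusted over the list alone; adjusted p = 0.00188, and adjusted p = 0.554 with an estimated correlation). Branched-chain amino acid catabolism lay lower by -0.14 with 1 of 19, Ivd at -0.28 (1 adjusted over the list alone; adjusted p = 0.00905, and adjusted p = 0.454 with an estimated correlation). Citric acid cycle enzymes lay lower by -0.12 with 0 of 15 (0 adjusted over the list alone; adjusted p = 0.0137, and adjusted p = 0.554 with an estimated correlation). The calls of the amino acid and citric acid cycle lists were lost without old HCR exhausted replicate 1, an array that stood apart. Macrophage markers had 4 of 10 members higher, C1qb and Lyve1 both at 0.79, Cd14 at 0.63 and Csf1r at 0.62 (4 adjusted over the list alone; adjusted p = 9.1e-07, and adjusted p = 0.119 with an estimated correlation).

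Old LCR rats showed 70 rises and 134 falls. Egr1 rose by 2.01 ± 0.39, Apold1 by 1.91 ± 0.34 and Fos by 1.84 ± 0.44. Immediate early genes had 9 of 25 members higher and 1 lower, Rrad at -2.57 (12 and 1 adjusted over the list alone; adjusted p = 2.43e-10, and adjusted p = 0.065 with an estimated correlation). The named falls were larger than in the other strata: Ampd3, the erythrocyte-type AMP deaminase, fell by 2.76 ± 0.47, the transmembrane glycoprotein gene Gpnmb by 2.76 ± 0.49 and Th, encoding tyrosine hydroxylase, by 2.63 ± 0.43, each lower in 6 of 6 arrays. Genes of denervation and the neuromuscular junction had 4 of 15 members lower and none higher (9 adjusted over the list alone), with Myog at -2.17, Gadd45a at -1.76, Chrna1 at -1.64 and Hdac4 at -0.90. The list was lower as a whole (adjusted p = 9.58e-08, and adjusted p = 0.065 with an estimated correlation). Their mean level was 8.19 ± 0.60 (SD, n = 6) at rest, with arrays from 7.44 to 8.82, and 7.34 ± 0.33 after the run. Tendon markers had no member past the threshold (2 lower adjusted over the list alone) at a median of -0.86 (adjusted p = 0.00289, and adjusted p = 0.236 with an estimated correlation). Their rest means were 7.05 and 7.30 in replicates 1 and 6 and between 5.35 and 5.85 in the other 4. Without single arrays the median ranged from -1.07 to -0.47 for tendon markers and from -0.95 to -0.37 for the denervation list, with no call lost. Fast muscle fibre markers lay higher by 0.11 with 0 of 7 past the threshold (4 adjusted over the list alone; adjusted p = 0.000475, and adjusted p = 0.065 with an estimated correlation). Endothelial markers lay higher by 0.19 with 0 of 9 (1 adjusted over the list alone; adjusted p = 0.000834, and adjusted p = 0.145 with an estimated correlation). The oxidative phosphorylation subunits lay higher by 0.12 with 1 of 60, Ndufa6 at 0.48 (3 adjusted over the list alone; adjusted p = 1.01e-08, and adjusted p = 0.341 with an estimated correlation). Glucocorticoid and FoxO target genes had 1 of 12 members higher, Klf15 at 0.47 (1 adjusted over the list alone; adjusted p = 0.00198, and adjusted p = 0.145 with an estimated correlation).

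The old LCR count of 204 was 383 without the 3 arrays that stood apart, 313 and 361 without rest replicates 2 and 3, 121 and 102 without rest replicates 5 and 6, and 129 without exhausted replicate 3. The Fos call was lost without rest replicate 6 or exhausted replicate 3. With only the 12 arrays of this stratum in the fit, 11 genes passed the threshold. Under relabelling of rest and exhausted arrays the highest count of the other arrangements was 159.

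**Figure D3:**
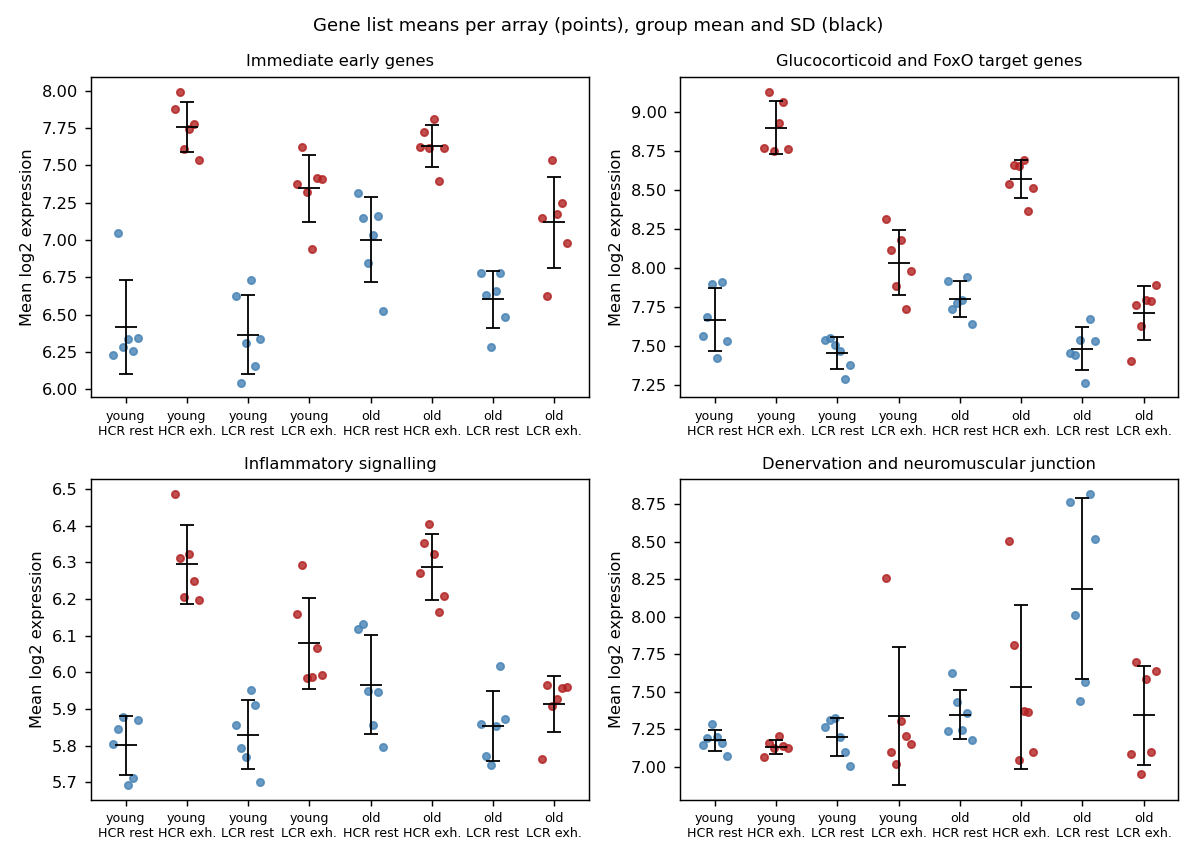
Mean log2 level of the measured members of 4 gene lists in each of the 48 arrays (points, rest in blue and exhausted in red) with the group mean and SD in black. Glucocorticoid and FoxO target genes went from 7.67 to 8.90 in young HCR and from 7.48 to 7.71 in old LCR; the denervation list fell from 8.19 to 7.34 in old LCR.

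Whether the lines responded differently was tested as the exercise response of HCR minus that of LCR, averaged over the ages. Running time and distance took no part in the model. A different response between lines or ages therefore cannot be told apart from a different length of the run. It differed for 201 genes, 102 with a higher and 99 with a lower response in HCR (126 and 88 after quantile normalization, 163 and 84 after median centring). The response of the protease gene Adamts9 was higher in HCR by 1.75 ± 0.19 (adjusted p = 3.72e-08): it rose by 1.97 in young and 1.63 in old HCR, and changed by 0.29 in young and -0.19 in old LCR. Hes1, a target of Notch, differed by 1.46 ± 0.16, Coq10b, of coenzyme Q transport, by 1.90 ± 0.22 and the TGF-beta corepressor gene Tgif1 by 1.34 ± 0.16. Mt2A differed by 3.13 ± 0.39, with a rise of 3.06 in young HCR and of 2.29 in old HCR. In LCR it fell in old rats (-1.89) and did not pass the threshold in young rats, at 0.99. Lower responses in HCR were found for the ubiquitin ligase gene Rnf125 at -0.83 ± 0.09, Aplnr at -1.47 ± 0.19, the ephrin gene Efna1 at -0.77 ± 0.11, Lpar6 at -1.18 ± 0.17 and Rgs4 at -0.99 ± 0.17. Lpar6 fell by 1.80 in young HCR and by 0.70 in young LCR.

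In HCR, glucocorticoid and FoxO target genes responded more by a median of 0.40, 6 of 12 members past the threshold (7 adjusted over the list alone; adjusted p = 1.3e-12, and 0.00112 with an estimated correlation), with Ddit4 at 1.70, Irs2 at 1.32, Errfi1 at 1.07 and Per1 at 1.01. Inflammatory signalling did so by 0.22, 3 of 15 members past the threshold (4 adjusted over the list alone; adjusted p = 4.18e-05, and 0.0168 with an estimated correlation), with Ptgs2 at 1.04. Macrophage markers responded more in HCR by 0.24 with 0 of 10 past the threshold (2 adjusted over the list alone; adjusted p = 0.00336, and adjusted p = 0.413 with an estimated correlation). Tendon markers were at 0.74 with 0 of 7 (4 adjusted over the list alone; adjusted p = 0.000521, and adjusted p = 0.191 with an estimated correlation). Smooth muscle and pericyte markers responded less by -0.32 with 0 of 7 (2 lower adjusted over the list alone; adjusted p = 0.0067, and adjusted p = 0.188 with an estimated correlation). Immediate early genes had 7 of 25 members with a higher and 1 with a lower response (9 and 4 adjusted over the list alone), Maff at 1.64, Junb at 1.53 and Nr4a2 at 1.47 among them (adjusted p = 0.00122, and adjusted p = 0.413 with an estimated correlation). Slow muscle fibre markers had none past the threshold (0 adjusted over the list alone) at a median of -0.47 (adjusted p = 0.0348, and adjusted p = 0.638 with an estimated correlation), a call lost without any of 15 arrays.

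The effect of age on the response was tested in the same way, and differed for 24 genes, 2 higher and 22 lower in old rats. After quantile normalization the numbers were 7 and 20, and after median centring 7 and 24. Trim63, a ubiquitin ligase of muscle atrophy, differed by -0.70 ± 0.12 (adjusted p = 0.00259), rising by 0.84 in young HCR and falling by 0.67 in old LCR. In young LCR and old HCR it was at 0.14 and 0.26, neither past the threshold. The response was also lower in old rats for the homeobox gene Zfhx2 at -0.62 ± 0.11, the urotensin receptor gene Uts2r at -1.40 ± 0.24, the mRNA-decay factor gene Zfp36l1 at -0.64 ± 0.12 and Relt at -0.79 ± 0.15. It was higher for Tfrc at 0.71 ± 0.16 and for Ssbp1, which binds mitochondrial DNA, at 0.33 ± 0.08. Immediate early genes responded less in old rats by a median of -0.52 with 1 of 25 members, Atf3 at -1.49, past the threshold (16 lower adjusted over the list alone; adjusted p = 1.56e-13, and 0.0446 with an estimated correlation). A weaker response was also seen for glucocorticoid and FoxO target genes, by -0.35 with 0 of 12 past the threshold (9 lower adjusted over the list alone; adjusted p = 1.17e-08, and 0.0158 with an estimated correlation). Tendon markers moved with these lists, at a median of -1.16 with 0 of 7 past the threshold (5 lower adjusted over the list alone; adjusted p = 9.73e-06, and adjusted p = 0.0686 with an estimated correlation).

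The count of 24 was unstable. Leaving out old LCR rest replicate 3 gave 91 genes, young LCR rest replicate 1 gave 72, old HCR exhausted replicates 1 and 2 gave 43 and 46, and old LCR rest replicate 4 gave 41. It was 13 without young HCR rest replicate 6, and 15 without young HCR rest replicate 4, young HCR rest replicate 5 or young LCR rest replicate 3. Leaving out old LCR exhausted replicate 1 or 6, young HCR exhausted replicate 4, young LCR exhausted replicate 1, old HCR rest replicate 5, old LCR rest replicate 1 or young LCR rest replicate 6 gave 14 each. The Tfrc call was lost without any of 4 arrays and the Ssbp1 call without any of 18.

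HCR rats were compared with LCR rats at rest, averaged over young and old (12 against 12 arrays), to find differences present before exercise. The amylase gene Amy1 was highest in HCR, by 1.69 ± 0.26. Slow-twitch contractile genes came next: the slow myosin heavy chain gene Myh7 was higher by 1.46 ± 0.37 (adjusted p = 0.00536), slow troponin T gene Tnnt1 by 1.37 ± 0.30, the light chain gene Myl3 by 1.32 ± 0.33, and troponin C gene Tnnc1 by 1.22 ± 0.29. The cytochrome P450 gene Cyp2j4 was higher by 1.20 ± 0.14, lactate dehydrogenase B (Ldhb) by 1.07 ± 0.19 and Acadsb, a dehydrogenase of branched-chain amino acid breakdown, by 1.07 ± 0.10 (adjusted p = 2.14e-10). The slow calcium pump gene Atp2a2 was higher by 1.03 ± 0.22. Apold1, the kinase gene Sbk2 and Crp completed the 12, between 0.94 and 0.97. Lower in HCR were Mybph, a myosin-binding protein, by -1.93 ± 0.30, the mitochondrial reductase gene Mtarc1 by -1.77 ± 0.16 (adjusted p = 3.79e-10), Th by -1.74 ± 0.30, Ostn, which encodes the secreted peptide musclin, by -1.47 ± 0.33, the desaturase gene Scd by -1.30 ± 0.30 and the imprinted noncoding RNA H19 by -1.18 ± 0.11. Tmem100, Hba-a3, Cst7, Slc51a, Ranbp3l and Tubb6 followed at -1.16 to -1.49. Each named gene lay on its side of the matching LCR mean in 10 to 12 of the 12 HCR arrays. Crp is a liver plasma protein gene, and its difference was 0.74, still past the threshold, with the liver mean as a covariate, while Alb was at 0.72 without passing the threshold (adjusted p = 0.575). The Crp call was lost without any of 11 arrays, and after quantile normalization or median centring.

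Mitochondrial lists were higher in HCR. Of the oxidative phosphorylation subunits 42 of 60 were higher and none lower (50 adjusted over the list alone; 23 after quantile normalization and 16 after median centring, none lower in either), with Ndufa2 at 0.50, Ndufb8 at 0.42 and Atp5mg at 0.37. The list was higher as a whole (adjusted p = 5.07e-17, and adjusted p = 0.21 with an estimated correlation). Fatty acid oxidation enzymes had 17 of 19 members higher (18 adjusted over the list alone; 14 after either scaling), Eci2 at 0.64 and Acaa2 at 0.61 among them (adjusted p = 1.16e-13, and adjusted p = 0.183 with an estimated correlation). Branched-chain amino acid catabolism had 15 of 19 (18 adjusted over the list alone; 10 after quantile normalization and 8 after centring), with Bckdhb at 0.48 and Ppm1k at 0.44 beside Acadsb (adjusted p = 4.6e-12, and adjusted p = 0.105 with an estimated correlation). Citric acid cycle enzymes had 8 of 15 (11 adjusted over the list alone; 6 after quantile normalization and 4 after centring; adjusted p = 2.85e-06, and adjusted p = 0.259 with an estimated correlation). Mitochondrial ribosomal proteins had 28 of 61 higher and 1 lower (35 and 3 adjusted over the list alone; 9 and 3 after quantile normalization, 7 and 3 after centring; adjusted p = 1.61e-06, and adjusted p = 0.235 with an estimated correlation). Regulators of mitochondrial biogenesis had 5 of 13 higher (6 adjusted over the list alone), the coactivator gene Ppargc1b at 0.35, Perm1 at 0.33 and Esrra at 0.28 (adjusted p = 0.0172, and adjusted p = 0.262 with an estimated correlation; adjusted p = 0.111 after quantile normalization on top).

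Slow muscle fibre markers had 6 of 10 members higher in HCR at a median of 0.83 (6 adjusted over the list alone; adjusted p = 0.000617, and adjusted p = 0.36 with an estimated correlation). By contrast, fast muscle fibre markers had 1 of 7 lower, Myh4 at -0.11 (1 adjusted over the list alone; adjusted p = 0.228). With the mean of the slow markers as a covariate, 20 of the 42 oxidative phosphorylation subunits and 11 of the 17 fatty acid oxidation enzymes remained higher. Endothelial markers had 6 of 9 higher (7 adjusted over the list alone), Esam at 0.44 and Cdh5 at 0.42 (adjusted p = 0.01, and adjusted p = 0.262 with an estimated correlation). PPAR and fasting target genes had 8 of 18 higher and 1 lower (10 and 2 adjusted over the list alone; adjusted p = 0.0116, and adjusted p = 0.496 with an estimated correlation), a call lost without old LCR rest replicate 5. Glucocorticoid and FoxO target genes had 6 of 12 higher, Fkbp5 at 0.91 (7 adjusted over the list alone; adjusted p = 0.00984, and adjusted p = 0.262 with an estimated correlation). On the lower side, denervation and neuromuscular junction genes had 3 of 15 lower, Gadd45a at -1.11 and Chrna1 at -0.92 (4 adjusted over the list alone; adjusted p = 9.07e-06, and adjusted p = 0.183 with an estimated correlation). The tendon markers had 2 of 7 lower, Kera at -0.90 and Tnmd at -0.67 (4 adjusted over the list alone; adjusted p = 0.000617, and adjusted p = 0.225 with an estimated correlation).

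In all, 1230 genes were higher and 192 lower in HCR at rest. After quantile normalization 476 were higher and 385 lower, and after median centring 376 and 521, so that the predominance of higher genes did not survive scaling.

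**Figure D4:**
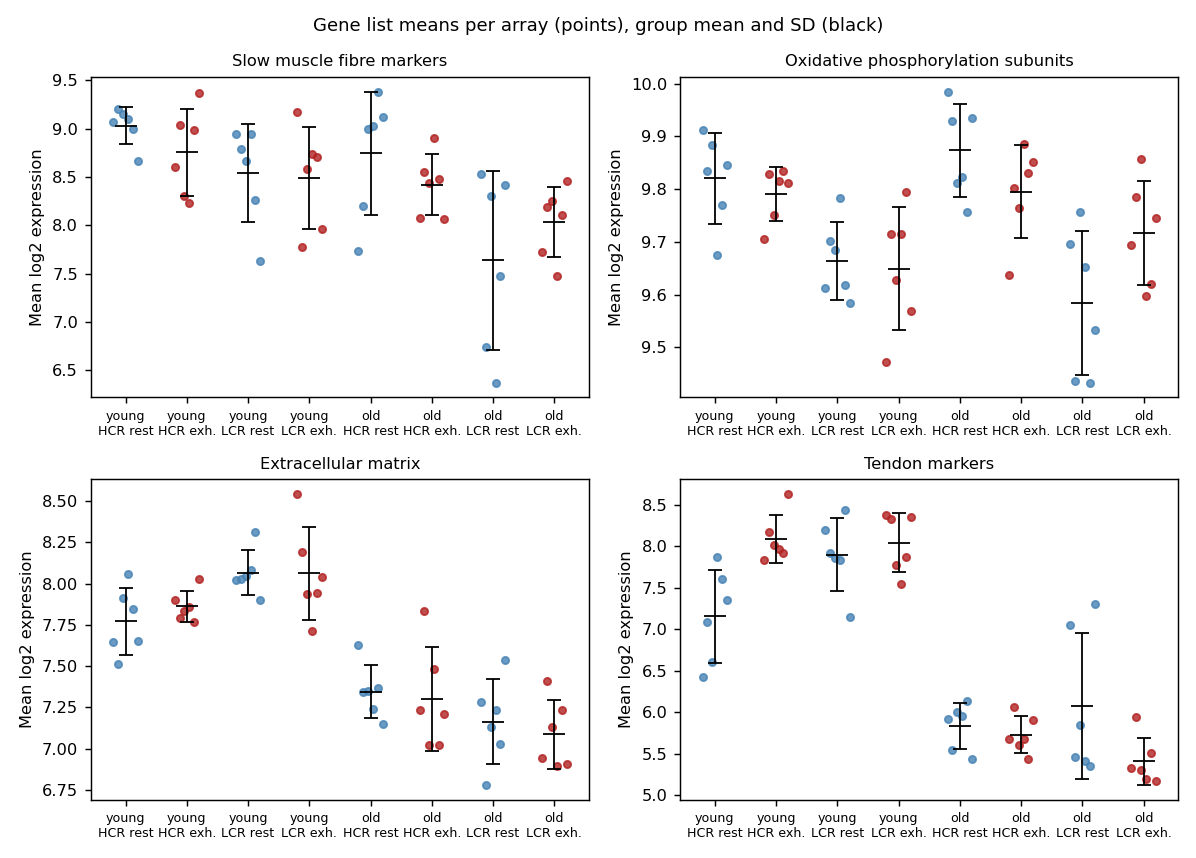
Mean log2 level of the measured members of 4 gene lists in each array (points, rest in blue and exhausted in red), with the group mean and SD in black. At rest slow fibre markers averaged 9.03 in young HCR, 8.54 in young LCR, 8.74 in old HCR and 7.64 in old LCR, and tendon markers 7.16, 7.90, 5.83 and 6.07.

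Between young HCR and young LCR at rest 145 genes differed, 110 higher and 35 lower. After quantile normalization 48 were higher and 48 lower, and after median centring 38 and 52. Amy1 was higher by 1.90 ± 0.36, Cyp2j4 by 1.26 ± 0.19 and the interferon-inducible GTPase gene Gvinp1 by 1.13 ± 0.17. Tekt1, of ciliary microtubules, was lower by -1.65 ± 0.22, Tmem100 by -1.60 ± 0.36 and Mtarc1 by -1.27 ± 0.23. Fatty acid oxidation enzymes had 5 of 19 members higher (16 adjusted over the list alone; adjusted p = 3.39e-14, and adjusted p = 0.195 with an estimated correlation). Slow muscle fibre markers had 0 of 10 past the threshold (0 adjusted over the list alone) at a median of 0.53 (adjusted p = 0.0414, and adjusted p = 0.739 with an estimated correlation). Without single arrays that median ranged from 0.35 to 0.65, and the call was lost without young HCR rest replicates 2, 3, 4 or 5 or young LCR rest replicates 5 or 6. Tendon markers had 1 of 7 lower, Tnmd at -1.16 (4 adjusted over the list alone; adjusted p = 4.34e-05, and adjusted p = 0.195 with an estimated correlation). The count of 145 was 83 and 88 without HCR rest replicates 1 and 6, and 68 and 45 without LCR rest replicates 5 and 6.

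Between old HCR and old LCR at rest 1173 genes differed, 984 higher and 189 lower. After quantile normalization 365 were higher and 342 lower, and after median centring 277 and 442. The median change of all genes was 0.08 as deposited and -0.03 after centring. Well above that shift, Myh7 was higher in HCR by 2.40 ± 0.52, Tnnt1 by 2.06 ± 0.43 and Tnnc1 by 1.92 ± 0.40, and Th was lower by -3.26 ± 0.43, Gpnmb by -2.38 ± 0.49 and Mybph by -2.33 ± 0.43. The p53 and senescence list had 3 of 10 members lower in HCR (3 adjusted over the list alone): Eda2r, a death-receptor family member, at -2.08, Gadd45a at -2.05 and the cell cycle inhibitor gene Cdkn2b (adjusted p = 9.2e-05, and 0.0211 with an estimated correlation). Denervation genes had 6 of 15 lower, with the calcium pump regulator gene Sln at -2.12, Chrna1 at -1.94 and Myog at -1.42 (8 adjusted over the list alone; adjusted p = 4.15e-08, and adjusted p = 0.0936 with an estimated correlation). Of the oxidative phosphorylation subunits 35 of 60 were higher (42 adjusted over the list alone; 14 after quantile normalization and 11 after median centring) at a median of 0.30 as deposited and 0.19 after centring (adjusted p = 3.55e-15, and adjusted p = 0.277 with an estimated correlation).

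After the run, HCR and LCR differed in 1157 genes, 877 higher and 280 lower in HCR. Quantile normalization gave 576 and 590, and median centring 546 and 612. Coq10b was higher by 2.10 ± 0.16, Arrdc2 by 2.07 ± 0.21 and Adamts9 by 2.04 ± 0.13, and Mybph was lower by -1.53 ± 0.30, the phospholipase gene Pla2g7 by -1.37 ± 0.26 and Hba-a3 by -1.37 ± 0.34, each in 11 or 12 of 12 arrays. All 12 glucocorticoid and FoxO target genes were higher in exhausted HCR rats, also adjusted over the list alone, at a median of 0.87 (adjusted p = 4.11e-19, and 3.5e-05 with an estimated correlation). Of 18 heat shock proteins and chaperones 10 were higher, Dnaja1 at 0.99 and Hsph1 at 0.86 (12 adjusted over the list alone; adjusted p = 1.79e-07, and adjusted p = 0.137 with an estimated correlation). In both states the same genes differed more often than chance would give: 423 were shared in the same direction, against 118 expected.

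Old rats were compared with young rats at rest, averaged over the lines (12 against 12 arrays), to find what aging changed in unexercised muscle. Genes of collagen fibres and tendon were among the largest falls. Kera fell by 3.15 ± 0.32 (adjusted p = 1.64e-09), as did Chad (-2.70 ± 0.32), and Fmod fell by 2.08 ± 0.27. Thbs4 fell by 1.67 ± 0.23 and Tnmd by 1.62 ± 0.19. Keratocan, chondroadherin and fibromodulin are matrix proteoglycans or related proteins, and Tnmd encodes tenomodulin of tendon cells. The chains of type I collagen fell with them, Col1a1 by 2.30 ± 0.18 (adjusted p = 9.07e-13) and Col1a2 by 2.07 ± 0.17. Further falls were of Angptl7 by 3.08 ± 0.32, the protease gene Adamts8 by 1.56 ± 0.22, Tfrc by 1.45 ± 0.11 (adjusted p = 8.55e-13), the BMP antagonist gene Chrdl1 by 1.37 ± 0.19 and Mettl21cl1 by 1.31 ± 0.19. All 12 were lower in 12 of 12 old arrays.

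Of the genes higher in old rats, Gpnmb rose by 2.30 ± 0.34, Ankrd1, a stretch-responsive ankyrin repeat gene, by 2.16 ± 0.50, Ampd3 by 2.16 ± 0.33, Rrad, a small GTPase of muscle, by 1.68 ± 0.32 and Sln by 1.66 ± 0.38. Eda2r rose by 1.47 ± 0.29 and the myogenic factor gene Myog by 1.45 ± 0.25; Rnase17, the cystatin gene Cst7, the tubulin gene Tubb6, Ostn and Prrt4 rose by between 1.39 and 1.87. These were higher in 9 to 12 of the 12 old arrays.

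Of 24 measured extracellular matrix genes 19 fell and none rose (20 adjusted over the list alone), at a median of -0.53, including the crosslinking enzyme gene Lox at -1.25 and Lum at -1.07 (adjusted p = 7.55e-22, and 0.0194 with an estimated correlation). Fibroblast and fibro-adipogenic markers had 8 of 10 lower (8 adjusted over the list alone; adjusted p = 1.42e-12, and 0.0194 with an estimated correlation). Tendon markers moved with both, 5 of 7 lower at a median of -1.67 (5 adjusted over the list alone; adjusted p = 4.08e-08, and 0.0194 with an estimated correlation). With the tendon markers' mean as a covariate 2 of the 19 matrix genes remained lower, but that mean itself nearly separated the ages at rest (5.35 to 7.30 in old and 6.43 to 8.44 in young arrays). Denervation and neuromuscular junction genes had 7 of 15 higher, with Gadd45a at 1.28 beside Ankrd1, Sln and Myog (8 adjusted over the list alone; adjusted p = 2.68e-05, and adjusted p = 0.13 with an estimated correlation). The p53 and senescence list had 4 of 10 higher and 1 lower, Cdkn2b at 0.81 and Phlda3 at 0.58 among them (4 and 1 adjusted over the list alone; adjusted p = 0.0175, and adjusted p = 0.13 with an estimated correlation). Genes of ubiquitin, autophagy and atrophy had 4 of 14 higher, the cathepsin gene Ctsl at 0.64 and Trim63 at 0.41 (4 adjusted over the list alone; adjusted p = 0.00373, and adjusted p = 0.131 with an estimated correlation). Heat shock proteins and chaperones had 6 of 18 higher and 1 lower, Hspa4l at 0.66 and Hspb7 at 0.60 (6 and 2 adjusted over the list alone; adjusted p = 0.000385, and adjusted p = 0.245 with an estimated correlation).

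Immediate early genes had 8 of 25 members higher in old rats at rest, Rrad, Atf3 at 1.13 and Fos at 0.91 (12 adjusted over the list alone; adjusted p = 1.5e-07, and adjusted p = 0.13 with an estimated correlation). Macrophage markers had 5 of 10 lower, Cd14 at -0.70 and Csf1r at -0.60 (6 adjusted over the list alone; adjusted p = 0.000357, and adjusted p = 0.245 with an estimated correlation). Slow muscle fibre markers had 1 of 10 lower, Ankrd2 at -1.17 (4 adjusted over the list alone; adjusted p = 0.00373, and adjusted p = 0.43 with an estimated correlation). The metabolic lists showed few changes: oxidative phosphorylation subunits had 1 of 60 higher and 2 lower (adjusted p = 0.746) and citric acid cycle enzymes 1 of 15 lower (adjusted p = 0.0632). Branched-chain amino acid catabolism had 0 of 19 past the threshold (adjusted p = 0.589) and fatty acid oxidation enzymes 2 of 19 higher (2 adjusted over the list alone; adjusted p = 0.0436, and adjusted p = 0.686 with an estimated correlation), a call lost without any of 13 arrays. In all 526 genes were higher and 791 lower in old rats, against 678 and 744 after quantile normalization and 676 and 720 after median centring.

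In HCR alone 165 genes were higher and 158 lower in old rats, against 183 and 207 after quantile normalization. Fos was higher by 1.88 ± 0.44, Atf3, a stress-induced transcription factor, by 1.72 ± 0.35 and Egr1 by 1.42 ± 0.39, while Kera fell by 2.83 ± 0.45, Angptl7 by 2.68 ± 0.46 and Chad by 2.37 ± 0.45. Extracellular matrix genes had 7 of 24 lower (12 adjusted over the list alone; adjusted p = 1.43e-09, and adjusted p = 0.257 with an estimated correlation), beside tendon markers with 5 of 7 lower (5 adjusted over the list alone; adjusted p = 7.5e-07, and adjusted p = 0.0857 with an estimated correlation). The count of 323 was 178, 135 and 206 without old HCR rest replicates 1, 2 and 6, and 123 and 173 without young HCR rest replicates 4 and 5. The Egr1 call was lost without any of 8 arrays.

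In LCR alone 273 genes were higher and 588 lower in old rats. Quantile normalization gave 427 and 504, and median centring 425 and 446. Gpnmb rose by 3.53 ± 0.49, Ampd3 by 3.52 ± 0.47, followed by Sln (adjusted p = 0.000146). Angptl7 and Kera both fell by 3.48, with SE of 0.46 and 0.45, and Chad by 3.03 ± 0.45. Here 21 of 24 extracellular matrix genes fell (22 adjusted over the list alone; adjusted p = 4.23e-26, and 0.0157 with an estimated correlation), together with 5 of 7 tendon markers (5 adjusted over the list alone; adjusted p = 1.76e-07, and 0.0293 with an estimated correlation). Denervation genes had 8 of 15 higher, Ankrd1 at 2.90 and Myog at 2.28 (8 higher and 1 lower adjusted over the list alone; adjusted p = 4.84e-08, and 0.0387 with an estimated correlation). The p53 and senescence list had 4 of 10 higher, Eda2r at 2.55 and Gadd45a at 2.22 (4 adjusted over the list alone, camera adjusted p = 0.000222, and 0.0157 with an estimated correlation). Both rises rest on the old LCR rest arrays. The same arrays enter the fall after the run in old LCR and the line difference in old rats. Among exhausted LCR rats the means of old and young were 7.34 and 7.34 for denervation genes, and 6.71 and 6.73 for the p53 list. Slow muscle fibre markers had 5 of 10 lower, Myh7 at -1.97 and Tnnt1 at -1.34 (6 adjusted over the list alone; adjusted p = 0.0012, and adjusted p = 0.384 with an estimated correlation).

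Among exhausted rats 247 genes were higher and 780 lower in old animals. Quantile normalization gave 559 and 607, and median centring 562 and 584. Angptl7 fell by 4.35 ± 0.32, Kera by 4.32 ± 0.32 and Chad by 4.14 ± 0.32, and Cst7 was higher by 1.51 ± 0.28, the interferon-inducible Gbp1 by 1.08 ± 0.30 and the clock output gene Dbp by 1.02 ± 0.18. Extracellular matrix genes had 22 of 24 lower (22 adjusted over the list alone; adjusted p = 6.34e-29, and 0.00871 with an estimated correlation), next to 5 of 7 tendon markers at a median of -3.01 (5 adjusted over the list alone; adjusted p = 5.14e-16, and 0.00111 with an estimated correlation). Of glucocorticoid and FoxO target genes 5 of 12 were lower, Ddit4 at -0.72 and Irs2 at -0.61 (8 adjusted over the list alone; adjusted p = 0.000208, and adjusted p = 0.0984 with an estimated correlation). The tendon markers' mean separated the ages completely here, from 5.17 to 6.06 in old and from 7.55 to 8.63 in young arrays, so that no adjustment for it could tell age and tendon apart. In both states 474 genes differed with age in the same direction, against 78.1 expected by chance.

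Whether aging differed between the lines at rest was tested directly. It did for 6 genes, 3 in each direction. Quantile normalization gave 5 and 8, and median centring 2 and 7. Th differed by -3.05 ± 0.61 (adjusted p = 0.0308): it was higher by 2.94 in old than in young LCR and by -0.12 in HCR. The smooth muscle gene Lmod1 differed by 0.98 ± 0.20, the matrix protein gene Sparc by 0.80 ± 0.16, Tekt1 by 1.47 ± 0.30, the potassium channel gene Kcnq5 by -1.01 ± 0.22 and Tcp11l1 by -0.86 ± 0.18. None of these 6 calls remained without a filter on dim genes, where the count was 0. The count was also 0 without any of old HCR rest replicates 1 and 5, old LCR rest replicate 5, young HCR rest replicates 5 and 6, and young LCR rest replicates 2, 3, 5 and 6, and it was 77 without old LCR rest replicate 3. It was 18 and 22 without old HCR rest replicates 2 and 3, 14 without young LCR exhausted replicate 1, 12 without old LCR rest replicate 2 or young HCR exhausted replicate 1, and 11 without young HCR rest replicate 1. It was 10 without young HCR rest replicate 3 or old HCR exhausted replicate 1, 3 without young LCR rest replicate 4, 2 without old LCR rest replicate 6, and 1 without old HCR rest replicate 4 or old LCR rest replicate 4. The p53 and senescence list rose less with age in HCR than in LCR by a median of -0.35, with 0 of 10 past the threshold (3 lower adjusted over the list alone; adjusted p = 0.00015, and 0.0189 with an estimated correlation). The extracellular matrix list had Sparc alone past the threshold (5 adjusted over the list alone; adjusted p = 4.33e-09, and adjusted p = 0.448 with an estimated correlation).

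The last comparison asked whether the difference between the lines' responses changed with age. By limma 0 genes passed the threshold, 682 had an unadjusted p below 0.05, and the smallest adjusted p was 0.141. A single array mattered: 1 gene passed without old LCR rest replicate 2 or without young LCR exhausted replicate 1, and 17 without old LCR rest replicate 3. The p53 and senescence list lay higher by a median of 0.67, led by Eda2r at 3.02 and Gadd45a at 2.45, with 0 of 10 past the threshold (2 higher adjusted over the list alone; adjusted p = 2.31e-05, and 0.00685 with an estimated correlation). Denervation genes lay higher by 0.85, with 0 of 15 past the threshold (6 higher and 1 lower adjusted over the list alone; adjusted p = 1.31e-06, and adjusted p = 0.157 with an estimated correlation).

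Changes in different strata were set side by side over the 9558 genes, which are not independent replicates. The exercise response of young HCR correlated with that of old HCR at r = 0.62 (Spearman's rho 0.44) and with that of young LCR at r = 0.54 (rho 0.44). In all, 193 genes passed the threshold in young and old HCR in the same direction against 12.9 expected, and 71 in young HCR and young LCR against 4.21. Correlations of old LCR were lower, at r = 0.18 with young HCR, 0.15 with young LCR and 0.08 with old HCR (rho 0.15, 0.13 and 0.06). Without single arrays these r ranged from 0.13 to 0.22, from 0.10 to 0.24 and from 0.02 to 0.14. Of 100 relabellings with the real one included, 1, 1, 2, 18 and 48 gave an r as large for these 5 pairs in the order given. Whether the correlations differ from each other was not tested. By genes past the threshold, old LCR shared 16 with young LCR in the same direction against 0.753 expected, and 0 went opposite ways. With old HCR it shared 16 against 3.30, and 3 went opposite ways against 3.13. The line difference at rest correlated between young and old at r = 0.39 (rho 0.36), and the age difference between HCR and LCR at r = 0.51 (rho 0.40), with 1 of 100 relabellings as large for each. Averages for line and age at rest correlated at r = -0.12 (rho -0.05), which 55 of 100 relabellings matched.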

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

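The relabelling tests of all 17 comparisons and the test of a fall common to all strata were chosen only after the results were seen; leaving out the 3 arrays that stood apart and the tendon and liver covariates were added after the data were seen.

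Liver transcripts such as Alb were lower in exhausted rats, by a median of -0.70 over 11 transcripts that stood out. Liver RNA in some rest arrays, brought in from outside the muscle, was tested with 17 further liver transcripts: after removal of group means their array mean followed that of the 11 at r = 0.959 (Spearman's rho 0.858, permutation p = 1e-05 for each, the smallest that 1e+05 permutations can give), and at r = 0.929 without the 2 arrays farthest from the median. Of the 17, 16 were lower in exhausted arrays, by a median of -0.48, although 1 passed the threshold, and Alb ranged from 4.30 to 12.4 over the arrays. The 3 arrays apart were not the cause, since the median without them was -0.62, a ratio of 0.884. The values are in line with liver RNA in some samples at the r of 0.959; where it came from was not tested, and an effect of the run itself remains open, as untested.

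Tendon and collagen transcripts were lower in old rats at rest, 19 extracellular matrix genes among them. With the tendon markers' mean as a covariate 2 of the 19 stayed lower, Col1a1 at -1.37 (adjusted p = 0.00227) and Col1a2 at -1.02 (adjusted p = 0.00529), and the median of the 19 went from -0.64 to -0.23 while the median SE grew from 0.11 to 0.17. Among 3 basement membrane collagens, which are not tendon markers, Col15a1 at -0.52 (adjusted p = 4.33e-05) and Col4a2 at -0.21 (adjusted p = 0.0376) were lower and Col4a1 at -0.11 was not past the threshold (adjusted p = 0.315). A smaller share of tendon tissue and a lower expression of matrix genes with age cannot be told apart, because tendon markers are themselves matrix genes and their mean nearly separates the ages. The arrays apart were excluded as the cause, as 17 of the 19 stayed lower without them.

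Denervation and neuromuscular junction genes were lower in exhausted than in rested old LCR rats, by a mean of -0.85 ± 0.28 (SE). A single rest array was excluded as the only cause, since the smallest change was -0.72 without old LCR rest replicate 5, a ratio of 0.851. Several animals together were not addressed: rest replicates 1, 5 and 6 were at 8.77, 8.82 and 8.52, and replicates 2, 3 and 4 at 8.02, 7.44 and 7.57. Of the arrays apart only old LCR rest replicate 2 enters this comparison. It lies below the rest mean, so that leaving it out could only enlarge the fall (-0.88, a ratio of 1.04), and this test decides nothing. A fall after the run common to all strata was excluded too, by a mean change of 0.0934 ± 0.10 over the other 3 strata. Rested and exhausted rats were different animals, so that an effect of the run and differences between the animals sampled remain open.

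Some arrays lay far from the other 5 of their group in a list mean, which chance alone gives in about 1 in 20 groups; here it was so in 20 of 256 list and group pairs (7.81%). Above their group were young HCR rest replicate 2 in immediate early genes (7.05, nearest other 6.34), old LCR exhausted replicate 3 in mitochondrial biogenesis regulators (7.90 against 7.81) and in heat shock proteins and chaperones (9.39 against 9.06). Antigen presentation and complement stood high in young HCR rest replicate 3 (6.90 against 6.54) and old HCR rest replicate 1 (7.02 against 6.64). The same held for denervation genes in young LCR exhausted replicate 1 (8.26 against 7.31) and endothelial markers in young HCR exhausted replicate 2 (7.80 against 7.62). Cytosolic ribosomal proteins were high in old HCR exhausted replicate 4 (8.10 against 7.91) and old LCR exhausted replicate 2 (8.01 against 7.88), and adipocyte markers in old LCR rest replicate 6 (6.24 against 5.85).

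Below their group were old HCR exhausted replicate 1 in citric acid cycle enzymes (10.89 against 11.07) and branched-chain amino acid catabolism (9.14 against 9.32), and young HCR exhausted replicate 1 in cytosolic ribosomal proteins (7.72 against 7.83). So were young LCR exhausted replicate 5 in ubiquitin and autophagy genes (8.79 against 8.95), old LCR exhausted replicate 1 in inflammatory signalling (5.76 against 5.91) and old HCR rest replicate 5 in hypoxia and angiogenesis (7.96 against 8.07). Slow fibre markers were low in young HCR rest replicate 6 (8.66), the array whose title names 2 animals, and fast fibre markers in young HCR rest replicate 5 (12.78 against 12.83). Satellite cell markers were low in old LCR exhausted replicate 4 (5.97 against 6.20) and adipocyte markers in young LCR rest replicate 1 (5.28 against 5.50).

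Over 93 named genes, 79 of 744 gene and group pairs (10.6%) had such an array. The named genes are not independent, so that this share cannot be set against the 1 in 20 that chance gives. It was the same array in at least 5 genes for 6 arrays: old LCR rest replicate 2, young HCR rest replicate 3 and young LCR exhausted replicate 1 in 9 genes each, old LCR rest replicate 3 in 7, old HCR exhausted replicate 5 in 6 and young LCR rest replicate 6 in 5. In old LCR rest replicate 2 and young HCR rest replicate 3 these included the liver plasma protein genes Alb, Apob, C3, Gc, Pzp and Serpina3c.

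Differences between groups in the size of an effect were tested as interactions. The response to the run differed between the lines for 201 genes, led by Adamts9 (1.75), Hes1 (1.46), Coq10b (1.90), Tgif1 (1.34) and Mt2A (3.13) with a higher response in HCR and Rnf125 (-0.83), Aplnr (-1.47), Efna1 (-0.77), Lpar6 (-1.18) and Rgs4 (-0.99) with a lower one. It differed between the ages for 24 genes, led by Tfrc (0.71), Ssbp1 (0.33), Trim63 (-0.70), Zfhx2 (-0.62), Uts2r (-1.40), Zfp36l1 (-0.64) and Relt (-0.79). Aging differed between the lines for 6 genes: Lmod1 (0.98), Sparc (0.80), Tekt1 (1.47), Th (-3.05), Kcnq5 (-1.01) and Tcp11l1 (-0.86).

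Of the gene lists, 17 differed in response between the lines, 12 between the ages, 8 differed in aging between the lines and 9 in the interaction of all 3 factors. With an estimated correlation 2, 2, 1 and 1 of them remained. These were glucocorticoid and FoxO target genes (median 0.40) and inflammatory signalling (0.22) between lines, immediate early genes (-0.52) and glucocorticoid and FoxO target genes (-0.35) between ages, and p53 and senescence genes in the last pair (-0.35 and 0.67).

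Relabelled arrays show how often chance gives each count or more, from 100 arrangements with the real one included. For 15 comparisons 1 of 100, the real one, gave as many genes. With 100 arrangements for each of 17 comparisons this does not exclude chance. After exercise the real counts and the highest of the others were 1542 and 171 over all strata, 830 and 246 in young HCR, 90 and 15 in young LCR, 301 and 64 in old HCR, and 204 and 159 in old LCR. Between the lines they were 1422 and 229 at rest, 145 and 2 in young, 1173 and 621 in old, and 1157 and 41 after the run. Between the ages they were 1317 and 14 at rest, 323 and 18 in HCR, 861 and 144 in LCR, and 1027 and 31 after the run. For the difference in response they were 201 and 4 between lines and 24 and 1 between ages.

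Nor was chance excluded for aging in HCR against LCR, where 5 of 100 arrangements gave at least the real count of 6. The highest other count of 378 points to a structure of the samples. An arrangement that exchanges the lines at one age carries the difference between the lines into this contrast, so that the structure need not lie outside the groups; it was not tested. For the interaction of all 3 factors the real count was 0, which 100 of 100 arrangements reach by construction, so that nothing follows about chance; the highest other count was 1.

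Probe sets without a single gene name, 21861 in all with 11882 above the filter, took no part in the comparisons. Tested in the same model, 999 of them changed after exercise (460 up and 539 down), 554 differed between HCR and LCR at rest (445 higher and 109 lower) and 653 between old and young at rest (305 higher and 348 lower).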

How the results depend on the processing

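Leaving out the 3 arrays apart and the tendon and liver covariates were chosen after the data were seen. No named gene reversed. Which direction held more genes did reverse after median centring for exercise (822 higher and 659 lower), exercise in old HCR (191 and 83), the lines at rest (376 and 521), in young (38 and 52), in old (277 and 442) and after the run (546 and 612), and age in HCR (173 and 220). The cause of the changes was not tested except where stated.

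Without a filter on dim genes more genes shared the adjustment, and the counts were 82 for HCR against LCR in young rats, 188 for age in HCR, 13 for age by exercise and 0 for line by age. A stricter filter gave 60 and 24 for these interactions. Quantile normalization gave 861 genes for HCR against LCR, 96 in young, 707 in old and 13 for line by age; centring gave 897, 90 and 719 for the first 3. Array weights gave 186 for exercise in young LCR, 331 in old LCR, 268 for the lines in young rats, 335 for line by exercise, 86 for age by exercise, 70 for line by age and 3 for the interaction of all 3 factors. An intensity trend with a robust prior gave 18 for line by age. The first principal component of the residuals gave 40 for age by exercise and 12 for line by age.

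With the slow fibre mean as a covariate the line counts were 634, 86 in young and 607 in old, with 44 for age by exercise and 19 for line by age. The adipocyte mean gave 1 for the interaction of all 3 factors. Without the 3 arrays apart there were 383 genes for exercise in old LCR, 244 for the lines in young rats and 24 for line by age. The tendon mean gave 64 for exercise in old LCR, 176, 18 and 257 for age over all, in HCR and in LCR, 0 for age after the run, 0 for age by exercise and 42 for line by age. The tendon mean separates or nearly separates the ages, so that the loss of age calls follows largely from the construction of that model. With it the larger direction also changed for age (121 higher and 55 lower), age in LCR (159 and 98) and exercise in young HCR (318 and 425).

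Fits to only the 12 arrays compared, with fewer degrees of freedom, gave 41, 118 and 11 for exercise in young LCR, old HCR and old LCR, 76 and 324 for the lines in young and old, and 177 and 439 for age in HCR and LCR. An additive model, which averages over more arrays, gave 2221 for the lines and 2069 for age.

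With the tendon mean as a covariate 5 list results turned to the opposite direction in the list test, none past the threshold afterwards. Their medians were, for slow muscle fibre markers, 0.19 for age and -0.15 for age in LCR, where the sign of the median itself did not change. For age after the run they were -0.0317 for oxidative phosphorylation subunits, 0.16 for fibroblast and fibro-adipogenic markers and 0.25 for macrophage markers.

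Leaving out each array in turn gave 1394 to 1862 genes for exercise, 622 to 940 in young HCR, 45 to 141 in young LCR, 207 to 329 in old HCR and 102 to 361 in old LCR. For the lines it gave 1146 to 1544, 45 to 184 in young, 831 to 1323 in old and 1017 to 1232 after the run. For age it gave 1118 to 1512, 123 to 372 in HCR, 630 to 1078 in LCR and 904 to 1164 after the run. The interactions ranged from 172 to 267 (line by exercise), 13 to 91 (age by exercise), 0 to 77 (line by age) and 0 to 17 (all 3 factors).

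Of 155 named gene results, array weights, the residual component and the mean over probe sets kept all, as did a stricter filter for the 131 it left. The threshold was no longer passed by 24 of 144 with the tendon mean (markers in the covariate were left out), 12 of 48 with only the arrays compared, 6 of 147 with the slow fibre mean and 1 of 72 with the additive model. Of all 155 it was no longer passed by 14 without a filter, 10 with the liver mean, 7 without the 3 arrays apart, 5 with the adipocyte mean, 4 after centring, and 1 each after quantile normalization and with the intensity trend. Of 196 list results 163 were lost with an estimated correlation, 33 with a stricter filter, 23 with the adipocyte mean, 19 with array weights, 18 without the 3 arrays apart, 15 after quantile normalization, 12 after centring, 10 without a filter, 5 with the liver mean, 2 with the residual component and 1 with the mean over probe sets. With the tendon mean 40 of 186 were lost, the 5 that turned included, and with the slow fibre mean 12 of 190. The call of 52 of the 196 was lost without some single array. The signal over background of dim probe sets and the number of arrays limit these counts.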

Other observations

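Lipid synthesis genes were lower in old rats at rest, 6 of 15 past the threshold and none higher (8 adjusted over the list alone), at a median of -0.27 (adjusted p = 5.26e-05, and 0.0194 with an estimated correlation). The elongase gene Elovl6 was at -0.78, the desaturase genes Fads2 and Fads1 at -0.75 and -0.67 and Lpin1 at -0.47. The list was lower in HCR alone, with 3 members past the threshold (3 adjusted over the list alone; adjusted p = 0.0197 with an estimated correlation), and in LCR alone, with 6 (6 adjusted over the list alone; adjusted p = 0.0471 with an estimated correlation). With the tendon markers' mean as a covariate 1 of its members stayed lower. After exercise 3 of 15 fell, Scd2 at -0.40, Sqle at -0.27 and Fads1 at -0.21 (4 adjusted over the list alone; adjusted p = 0.384).

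The circadian clock list moved after exercise with members in both directions, 4 of 11 higher and 3 lower (4 and 3 adjusted over the list alone): Per1 at 1.26, Per2 at 0.76 and Nfil3 at 0.44 rose and Bmal1 fell (-0.33) (adjusted p = 0.0353, and adjusted p = 0.0801 with an estimated correlation). The list call was lost without old HCR exhausted replicate 1 or young HCR exhausted replicate 2. The hour of collection is not given in the labels. With age 3 of its members were higher and 4 lower (4 and 5 adjusted over the list alone), Dbp at 0.81 and Bmal1 at -0.59 among them (adjusted p = 0.877). Oxidative stress and metallothionein genes had 3 of 15 higher and 1 lower after exercise (3 and 1 adjusted over the list alone), with Mt2A at 1.11 and the glutathione peroxidase gene Gpx3 at 0.52 (adjusted p = 0.139). In the hypoxia and angiogenesis list 4 of 15 rose and 2 fell (4 and 4 adjusted over the list alone), Pfkfb3 at 0.58, Nos3 at 0.40 and Tek at -0.25 (adjusted p = 0.565). Glycolysis and glycogen metabolism had 2 of 16 higher and 1 lower (2 and 1 adjusted over the list alone; adjusted p = 0.139), with Pkm at 0.23 and Hk2 at -0.17.

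Further lists after exercise showed few changes. Antigen presentation and complement had 4 of 18 higher and 1 lower, C1qc at 0.34 and C3 at -0.87 (4 and 1 adjusted over the list alone; adjusted p = 0.0272, and adjusted p = 0.65 with an estimated correlation), a call lost without old LCR exhausted replicate 2 or old LCR rest replicate 3. Cytosolic ribosomal proteins had 10 of 90 higher and 3 lower (10 and 3 adjusted over the list alone; adjusted p = 0.0339, and adjusted p = 0.733 with an estimated correlation), a call lost without any of 9 arrays. Fast muscle fibre markers had 1 of 7 higher, Tnnt3 at 0.07 (2 adjusted over the list alone; adjusted p = 0.0172, and adjusted p = 0.247 with an estimated correlation). Endothelial markers had 3 of 9 higher and 2 lower, the tight junction gene Cldn5 at 0.69 (4 and 2 adjusted over the list alone; adjusted p = 0.243). Smooth muscle and pericyte markers had 1 of 7 higher and 3 lower, Kcnj8 at -0.41 and Pdgfrb at -0.26 (1 and 4 adjusted over the list alone; adjusted p = 0.229). Ubiquitin, autophagy and atrophy genes had 2 of 14 higher, Ulk1 at 0.21 (1 adjusted over the list alone; adjusted p = 0.423), and satellite cell markers 1 of 6 higher and 1 lower, Sdc4 at 0.51 and Vcam1 at -0.27 (2 and 1 adjusted over the list alone; adjusted p = 0.139). Regulators of mitochondrial biogenesis had 1 of 13 higher and 1 lower (1 and 1 adjusted over the list alone; adjusted p = 0.861).

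Lists with fewer than 5 measured members were not tested as lists. With age, the T, B and NK cell genes Cd4 and Nkg7 were at -0.67 and 0.47, the mast cell genes Cpa3 and Tpsb2 at -0.84 and -0.51, and the erythroid gene Hba-a1 at -0.74, each past the threshold. None of the 3 lymphocyte, 4 mast cell and 2 erythroid members changed after exercise, and 0 neutrophil markers were measured.

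Of the genes past the threshold both for line and for age at rest, 164 went opposite ways against 112 expected, and 80 the same way against 83.6 expected. Both comparisons use the same rest arrays, and over all genes 55 of 100 relabellings gave a correlation as large as the real one.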
